A study of Mus musculus with 41 samples.

How the data were processed

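The beta chain of the T cell receptor was sequenced from genomic DNA of mouse skin samples, with 1 library per animal and 41 libraries in 5 groups. Per the labels, DNA was isolated from whole tumours, amplified by a PCR in 2 steps and sequenced on an Illumina NextSeq instrument. The deposited counts are reads per CDR3 nucleotide sequence, each with its V and J segment calls; the CDR3 is the part of the receptor formed where V, D and J segments join. The deposited normalized clone counts are a score: each equals the read count times 1 factor per pair of V and J segment, as a whole number. In the files these factors were the same in all 41 libraries to within 1.57%, covered 208 pairs, and ranged from 0.256 to 85.6 with a median of 1.06; no scaling between libraries was found. The deposited fraction columns give each clone's share of the summed column of its library. How the authors made the factors, assembled the reads and filtered the clones is not stated. A second normalized column used factors from 0.292 to 19.4.

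The tables held 125465 clonotypes, from 309 to 8715 per library. Every CDR3 was in frame and without a stop, so the share of non-productive rearrangements, which had been planned as a measure, could not be computed. The clone numbers had gaps, and the listed clonotypes made up 47.3% to 69.2% of the numbers used in each library, so clones had been removed before deposition. The files named 21 V and 13 J segments, and all 34 symbols were found in the mouse reference gene table. The files name no genome build and that table holds no coordinates, so segments are given by symbol alone. Read totals ran from 32773 to 2367924 per library. Single-read clonotypes made up 13.5% to 46.7% of a library. PCR reads carried no molecular identifiers, so reads are not independent molecules and every Wilson 95% interval covers counting error only. Libraries were checked for shared nucleotide clonotypes in all 820 pairs, where the median was 0.253% of the clonotypes of a pair; the highest was 14.0% for paclitaxel 9 and combined treatment 5, then 3.29% for paclitaxel 10 and combined treatment 5, and no other pair exceeded 2.13%.

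Sequences called TRBV26 began 21 residues before the conserved cysteine in 98.9% of cases and were trimmed to it. A further 611 clonotypes (0.487%) did not begin with cysteine and were left out of the 2 measures that need that position, CDR3 length and the hydrophobic share. Where several V segments were listed for a clonotype, which was so for 3.66%, the first was used.

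For each library 8 repertoire measures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were clonality (1 minus the Shannon entropy of the normalized clone shares over its maximum, so that 0 means even clones), the share held by the 10 largest clones, the share of the largest clone, the share of expanded clones (each above 1%), the number of clonotypes at equal depth on the log2 scale, the log2 total of the normalized count, the mean CDR3 length over distinct clonotypes, and the percentage of distinct clonotypes with hydrophobic residues at CDR3 positions 6 and 7, counted from the cysteine. Equal depth meant thinning each library to 32773 reads, with the mean of 10 draws. Since no scaling between libraries was found, the total of the normalized count follows the reads sequenced per library. It is not a count of T cells. Group means were compared in 6 contrasts by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over all 48 tests and a threshold of 0.05. The interaction of paclitaxel and PMX-53 was tested by permuting residuals of the additive model 100000 times, adjusted over 8 measures.

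Segment usage was the percentage of distinct clonotypes with a segment. It was compared on log2(percent + 0.1) with limma 3.58.1 in R 4.3.3 with a mean-variance trend, for segments with a mean usage of at least 0.1%, adjusted within each contrast. Of the 21 V segments 20 were tested, and of the 13 J segments 12. For V segments in paclitaxel against control, the fit was tested on simulated data with the groups' sizes and the segments' real means and spreads, and not for other contrasts or J segments: 80% of segments with a change of 1 log2 unit and 98% with a change of 2 were called, beside 0.667% and 3.33% of unchanged segments. Lists of segments were fixed beforehand. List A held 9 V segments that are absent from the V-beta deletion haplotypes of some mouse strains. Whether the FVB mice of this series carry such a haplotype was not checked. Differences in list A are therefore not taken as changes in how these mice use their own segments. List B held the usual partners of the invariant NKT cell alpha chain, and list C the usual partners of the MAIT cell alpha chain. The lists overlap: TRBV13-2 of list B and TRBV13-1, TRBV13-2 and TRBV13-3 of list C are also in list A. Lists D and E held the J segments of cluster 1 and cluster 2, and list F held 13 pseudogene V segments. Summed list percentages were compared by exact permutation tests adjusted over 30 tests.

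Overlap between mice was the Jaccard index of clonotypes defined by V, J and CDR3 amino acids after thinning to equal depth, tested by relabelling mice 100000 times. Clonotypes found in at least 4 mice were compared by Fisher's exact test. Groups, contrasts, tests, lists and most alternative settings were chosen before the data were examined. The rule for naming segments took every segment past the threshold of a contrast, and in any case the 5 V and 3 J segments with the highest mean usage in control tumours. The rule for naming clonotypes took the 2 with the largest share in any 1 mouse of each group, those past the threshold of the Fisher tests up to 10 per contrast, and the 5 found in most mice. The alternatives chosen then were reads before normalization, thinning, an amino acid definition of clones, no single-read clones, removal of clonotypes at least 100 times more frequent in another library, a rank statistic, pairing of same-numbered animals, other pseudocounts and usage filters, weighting by abundance, fits with 2 groups, other overlap and presence rules, and leaving out each animal. Chosen after seeing the data were the second normalized column, leaving out 4 libraries under 100000 reads, leaving out list A segments, thinning for J usage and the lists, leaving out each animal for the lists, and an equal number of clonotypes for overlap. The labels name no batch, sequencing run or date. Matched blood samples, which the series also describes, were not among the files.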

Results

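The samples came from wild-type mice of the FVB strain with squamous cell carcinoma of the skin. Their labels give a postnatal age of 110 to 140, without a unit, in all groups. The treatment groups compared were: 8 control tumours, 10 tumours under paclitaxel, 9 under PMX-53 and 8 under both drugs. Paclitaxel, a microtubule-binding chemotherapy, was injected into a vein, 3 times per cycle and 4 days apart, at a dose of 12 mg/kg. PMX-53, a cyclic peptide that blocks the receptor of the complement fragment C5a, was given from a subcutaneous pump at 1.0 mg/kg per day starting on day 40, with tumours of about 50 mm3. A further 6 samples are named NTB untreated. Their labels give skin as tissue and primary tumour as source like the rest, and do not spell out the abbreviation. Below, tumour groups and tumour libraries mean the other 4 groups. This naming does not imply that NTB untreated samples held no tumour, which the labels leave unclear. Reads per library ranged from 544526 to 2367750 in control tumours, from 284335 to 2367924 under paclitaxel, from 51812 to 1908392 under PMX-53, from 32773 to 731014 under both drugs and from 406042 to 942794 in NTB untreated samples. The groups under PMX-53 therefore held the shallowest libraries.

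In control tumours a few clones held a large part of the repertoire. Clonality was 0.232 ± 0.0457 (SD, n = 8), the 10 largest clones held 23.8% ± 7.65 (SD, n = 8) of the normalized clone count, and clones above 1% together held 24.2% ± 8.45 (SD, n = 8). The V segments with the highest usage were TRBV24 with 18.2% ± 2.08 of distinct clonotypes, TRBV26 with 16.2% ± 3.40, TRBV1 with 13.9% ± 2.26, TRBV5 with 12.1% ± 1.28 and TRBV2 with 9.37% ± 1.26 (SD, n = 8 each). The leading J segments were TRBJ2-7 with 23.9% ± 1.44, TRBJ2-5 with 13.98% ± 1.27 and TRBJ2-3 with 10.9% ± 1.49 (SD, n = 8 each). The 13 pseudogene V segments of list F, chosen beforehand as a background, were absent from the files of all groups. Clones had been removed before deposition, so this absence does not measure how often segments were wrongly called. The 2 largest single clones of control tumours both used TRBV4 with TRBJ2-7. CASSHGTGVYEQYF held 13.045% of the normalized count of control 1 and 6.47% of its reads (Wilson 95% interval 6.41% to 6.52%). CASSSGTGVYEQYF held 12.0% of control 2 and 5.39% of its reads (Wilson 95% interval 5.35% to 5.43%).

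**Figure D1:**
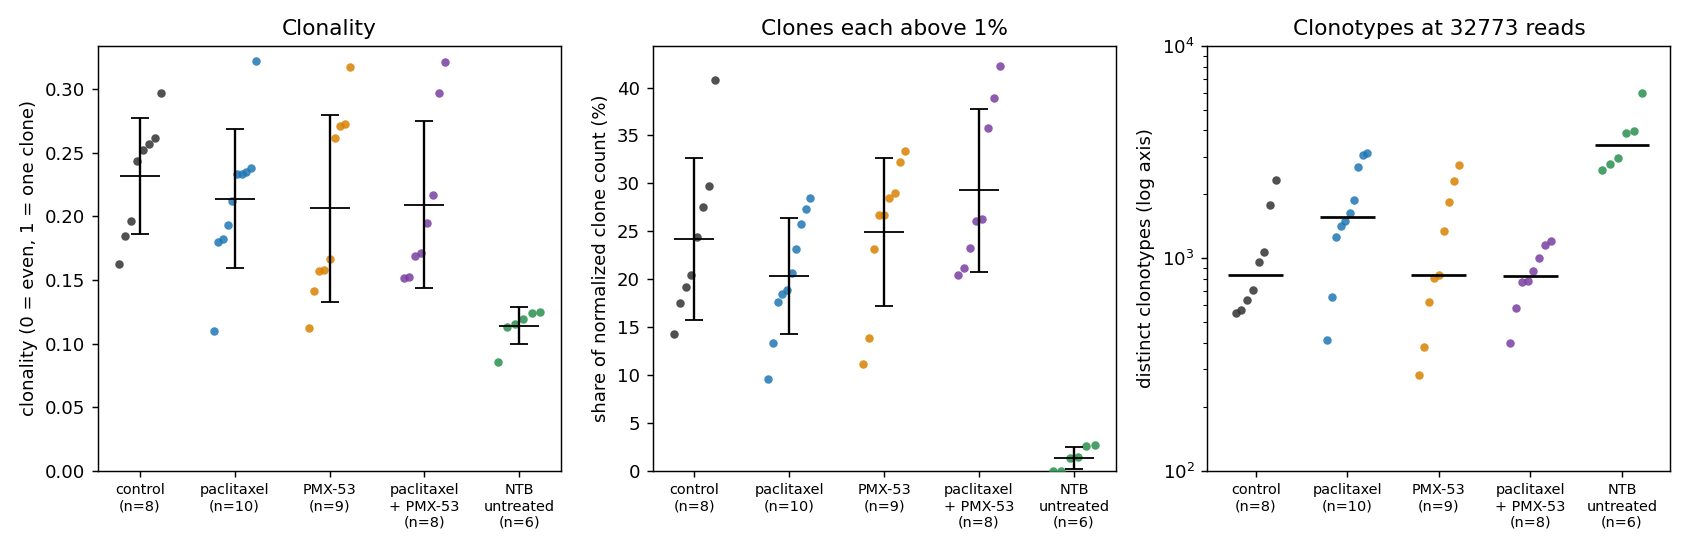
Clonality, the percentage of the normalized clone count held by clones above 1%, and the number of distinct clonotypes at 32773 reads (log axis), per library (points) and group. Black lines show mean and SD in the first 2 panels and the median in the third; the 6 NTB untreated libraries had clonality from 0.0857 to 0.125, all below the lowest control library at 0.163.

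The comparison of paclitaxel with control asks what chemotherapy alone does to the T cell clones of the tumour. Tumours under paclitaxel had a clonality of 0.214 ± 0.0547 (SD, n = 10) against 0.232 ± 0.0457 (SD, n = 8) in controls, and expanded clones held 20.3% ± 6.06 against 24.2% ± 8.45. At equal depth they held 1766 ± 939 clonotypes (SD, n = 10) against 1078 ± 648 (SD, n = 8). TRBV24 stood at 19.3% ± 2.22 and TRBV26 at 15.2% ± 4.22 of clonotypes, close to the control levels of 18.2% and 16.2%. The largest clones were TRBV26 TRBJ2-3 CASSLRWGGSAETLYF in paclitaxel 3, with 13.5% of the normalized count but 0.375% of reads (Wilson 95% interval 0.367% to 0.383%), and TRBV4 TRBJ2-7 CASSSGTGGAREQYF in paclitaxel 4, with 10.5% of the normalized count and 4.97% of reads (Wilson 95% interval 4.92% to 5.01%). None of the 8 measures passed the exact permutation test: the clonality difference was -0.0180 (adjusted p = 0.643), and the richness difference of 0.67 on the log2 scale had an adjusted p of 0.309. The limma fit called 0 of 20 V segments and 0 of 12 J segments, with 1 V and 2 J segments at an unadjusted p under 0.05. The V segments of list C, usual partners of the MAIT cell alpha chain, summed to 8.51% ± 1.49 (SD, n = 10) against 7.21% ± 0.548 (SD, n = 8), and the exact permutation test gave p = 0.0270 and an adjusted p of 0.162.

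The comparison of PMX-53 with control asks what blocking the C5a receptor does without chemotherapy. Clone sizes did not separate the groups: clonality was 0.206 ± 0.0738 (SD, n = 9), and expanded clones held 24.96% ± 7.73 (SD, n = 9) against 24.2% in controls. The segments of list C rose to 9.38% ± 1.49 of clonotypes (SD, n = 9) from 7.21% ± 0.548 (SD, n = 8), and TRBV19, their main member, stood at 7.69% ± 1.54 against 6.42% ± 0.871. TRBV12-1, a member of list A, fell to 0.512% ± 0.497 from 1.23% ± 0.252, a log2 change of -1.49 ± 0.44 (SE). The mean CDR3 was shorter, at 14.04 ± 0.0914 residues (SD, n = 9) against 14.20 ± 0.0573 (SD, n = 8). The largest clones of this group used TRBV4 with TRBJ2-7: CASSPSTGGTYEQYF held 26.8% of PMX-53 6 (12.9% of reads, Wilson 95% interval 12.8% to 12.9%) and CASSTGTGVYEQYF held 25.4% of PMX-53 8 (11.3% of reads, Wilson 95% interval 11.2% to 11.4%). By exact permutation test the list C difference of 2.17 points had an adjusted p of 0.005, with 9 of 9 libraries above the control mean, and the CDR3 length difference of -0.158 residues had an adjusted p of 0.0032, with 9 of 9 libraries below the control mean. Of the 4 members of list C limma called 0 over all segments and 0 adjusted over the list alone, the lowest unadjusted p being 0.0902 for TRBV13-2. Of the 8 tested members of list A, TRBV12-1 was called both over all segments (adjusted p = 0.0294) and adjusted over the list alone. TRBV12-1 clonotypes had a median of 1 read in both groups, and its log2 change was -0.08 at equal depth. At equal depth the CDR3 length difference was 0.00612 residues, and list C still passed with a difference of 1.88 points, as it did without PMX-53 9 (1.74 points), a library with 12.8% in list C. Without list A segments list C came down to TRBV19, whose difference of 1.29 points did not pass. The exact permutation test found no other difference in the 8 measures: the total normalized count was 19.23 on the log2 scale against 20.69, a difference of -1.46 (p = 0.0377, adjusted p = 0.129). Limma called 0 J segments, with 1 at an unadjusted p under 0.05.

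The comparison of both drugs with control asks how the combined treatment changes the repertoire. TRBV26 fell to 8.54% ± 3.53 of clonotypes (SD, n = 8) from 16.2% ± 3.40 (SD, n = 8), a log2 change of -0.995 ± 0.21 (SE), lower than the control mean in 8 of 8 libraries. List C rose to 9.72% ± 2.58 (SD, n = 8) from 7.21% ± 0.548 (SD, n = 8), with TRBV19 at 8.05% ± 2.16. The mean CDR3 length was 13.96 ± 0.0793 residues (SD, n = 8) against 14.20 ± 0.0573 (SD, n = 8), and the total normalized count was 18.34 on the log2 scale against 20.69. Expanded clones held 29.3% ± 8.47 (SD, n = 8), against 24.2% ± 8.45 (SD, n = 8), and clonality was 0.209 ± 0.0656 (SD, n = 8). The largest clones were TRBV4 TRBJ2-7 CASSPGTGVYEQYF in library 2 of this group, with 23.1% of the normalized count and 10.5% of reads (Wilson 95% interval 10.4% to 10.6%), and TRBV4 TRBJ2-7 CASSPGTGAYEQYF in library 6, with 17.1% and 9.19% of reads (Wilson 95% interval 9.12% to 9.26%). In limma TRBV26 had an adjusted p of 0.000351 and was the only V segment called; 0 J segments were called, with 2 at an unadjusted p under 0.05. The exact permutation tests gave an adjusted p of 0.0497 for list C, 0.0032 for CDR3 length (8 of 8 libraries below the control mean) and 0.0134 for the total count, a difference of -2.35 (8 of 8 below); of the 4 members of list C limma called 0 over all segments and 0 adjusted over the list alone, the lowest unadjusted p being 0.0525 for TRBV19. At equal depth TRBV26 changed by -0.55, list C differed by 1.84 points and CDR3 length by -0.0380 residues, of which only TRBV26 passed the threshold. Weighted by abundance TRBV26 changed by -0.20 and did not pass. Without the 4 libraries under 100000 reads the total differed by -1.22 and no longer passed, and without list A segments list C (TRBV19 alone) did not pass either. The total follows the reads sequenced, whose mean per library was 329645 under both drugs and 1243172 in control. Library 5 of this group shared 35.9% of its nucleotide clonotypes with paclitaxel 9. Without it TRBV26 (-0.93), list C (2.85 points), CDR3 length (-0.243 residues) and the total (-2.17) still passed against control. List C did not pass without any 1 of the 8 control libraries or without library 2, 3, 4, 7 or 8 of this group, its difference then being 1.92 to 2.63 points.

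**Figure D2:**
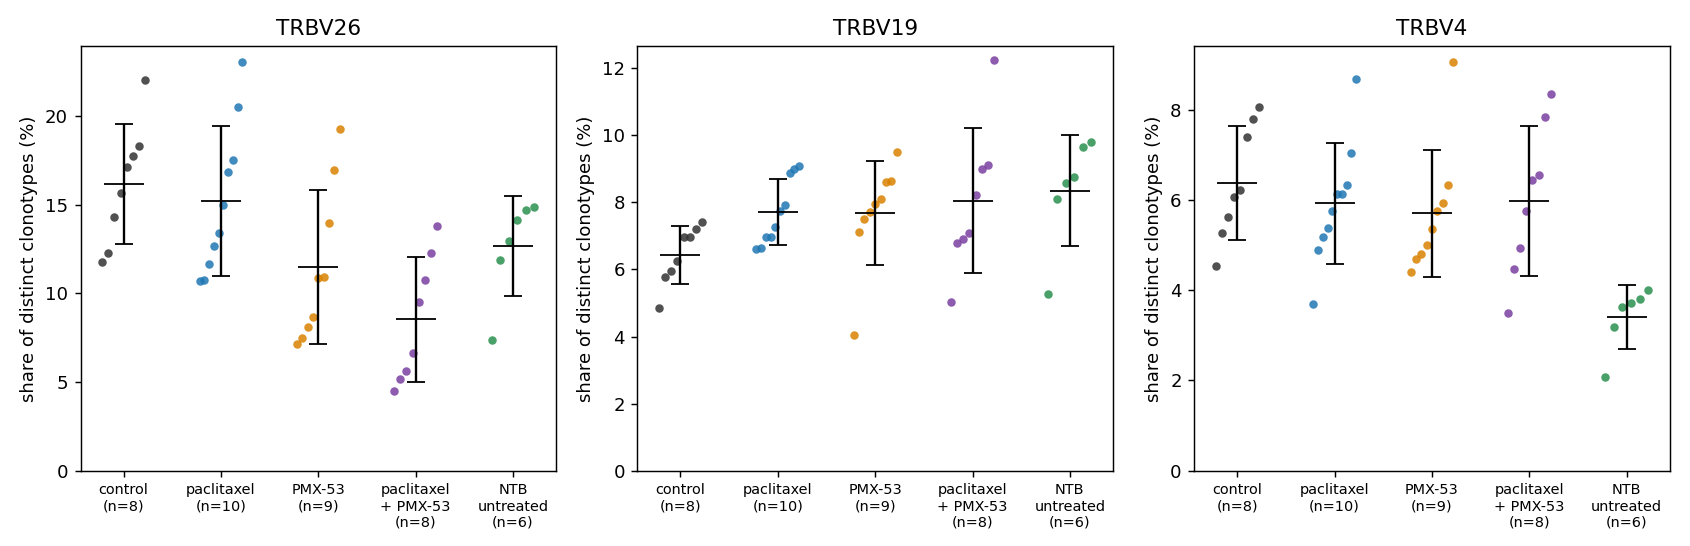
Usage of TRBV26, TRBV19 and TRBV4 as a percentage of distinct clonotypes, per library (points) and group, with mean and SD (black). TRBV26 averaged 8.54% under both drugs against 16.2% in control, a log2 change of -0.55 at equal depth and -0.20 when weighted by abundance, where it did not pass; TRBV4 averaged 3.40% in NTB untreated samples, with all 6 below the lowest control library at 4.54%.

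The comparison of both drugs with paclitaxel asks whether blocking the C5a receptor changes the clonal response to chemotherapy. Expanded clones held 29.3% ± 8.47 of the repertoire (SD, n = 8) with both drugs and 20.3% ± 6.06 (SD, n = 10) with paclitaxel, and the 10 largest clones 28.3% ± 8.46 against 20.8% ± 5.70. At equal depth there were 847 ± 274 clonotypes (SD, n = 8) against 1766 ± 939 (SD, n = 10). TRBV26 fell to 8.54% ± 3.53 of clonotypes from 15.2% ± 4.22, a log2 change of -0.89 ± 0.20 (SE), and TRBJ2-7 fell to 23.5% ± 3.04 from 26.2% ± 1.55, a log2 change of -0.16 ± 0.05 (SE). The mean CDR3 length was 13.96 ± 0.0793 residues (SD, n = 8) against 14.15 ± 0.117 (SD, n = 10), and clonality was 0.209 against 0.214. By exact permutation test the differences in expanded clones (8.95 points, p = 0.0183, adjusted p = 0.0731, 8 of 8 libraries above the paclitaxel mean), in the 10 largest clones (7.42 points, p = 0.0403, adjusted p = 0.129) and in richness (-0.90 on the log2 scale, p = 0.0297, adjusted p = 0.110) did not pass after adjustment. The total count, with a difference of -2.38 (adjusted p = 0.0168), and the CDR3 length, with -0.192 residues (adjusted p = 0.00836), passed the exact permutation test, each with 8 of 8 libraries below the paclitaxel mean. Limma gave TRBV26 an adjusted p of 0.000878 and TRBJ2-7 one of 0.0479, lower in 8 and 7 of 8 libraries; TRBJ2-7 was the 1 member of list E called over all segments and the 1 called adjusted over the list alone. At equal depth TRBV26 (-0.21), TRBJ2-7 (-0.09) and CDR3 length (-0.0421 residues) did not pass, and TRBJ2-7 stood at 0.21 when weighted by abundance. The difference in expanded clones passed with the authors' second normalized column (11.1 points) and without paclitaxel 3 (9.86), combined treatment 3 (10.1) or combined treatment 5 (10.2), the library that shared clonotypes with paclitaxel 9. Without the 4 libraries under 100000 reads the total (-1.26), TRBV26 (-0.51), TRBJ2-7 (-0.09) and CDR3 length (-0.162 residues) did not pass. The total follows the reads sequenced, whose mean per library was 329645 with both drugs and 1363189 with paclitaxel.

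Both drugs against PMX-53 asks what paclitaxel adds when the C5a receptor is blocked. TRBJ2-1 fell to 9.99% ± 1.17 (SD, n = 8) from 11.6% ± 1.65 (SD, n = 9), a log2 change of -0.22 ± 0.07 (SE), lower in 8 of 8 libraries. TRBV26 stood at 8.54% ± 3.53 against 11.5% ± 4.35 and TRBV24 at 20.3% ± 1.79 against 19.6% ± 2.34. Expanded clones held 29.3% ± 8.47 (SD, n = 8) against 24.96% ± 7.73 (SD, n = 9). TRBJ2-1 had an adjusted p of 0.0434 in limma. In list E, TRBJ2-1 was the 1 segment called over all segments. Adjusted over the list alone 1 lower (TRBJ2-1) and 1 higher segment were called, the latter TRBJ2-2 with a log2 change of 0.21 (9.15% ± 1.66 against 7.82% ± 0.985). Limma called 0 of 20 V segments, with 1 at an unadjusted p under 0.05, and no repertoire measure passed the exact permutation test, the lowest adjusted p being 0.186 for CDR3 length. TRBJ2-1 did not pass in the fit of these 2 groups alone (-0.22) or without the libraries under 100000 reads (-0.10). Nor did it pass with same-numbered animals as blocks (-0.21) or weighted by abundance, where the change was larger (-0.46). The interaction of the 2 drugs, tested by permutation over all 4 tumour groups, passed for none of the 8 measures, the lowest adjusted p being 0.473. By permutation, for expanded clones it was 8.22 points (p = 0.111) and for richness -0.94 on the log2 scale (p = 0.118).

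NTB untreated samples differed from control tumours in most measures. Clonality was 0.114 ± 0.0145 (SD, n = 6) against 0.232 ± 0.0457 (SD, n = 8), the 10 largest clones held 6.09% ± 0.832 against 23.8% ± 7.65, and expanded clones held 1.33% ± 1.18 against 24.2% ± 8.45. At equal depth these samples had 3704 ± 1270 clonotypes (SD, n = 6) against 1078 ± 648 (SD, n = 8), which is 3.77-fold on the log2 mean. The V segments of list A were the most altered: 6 of the 8 tested members rose, among them TRBV13-2 to 3.14% ± 3.36 from 0.160% ± 0.127, TRBV13-1 to 1.67% ± 1.56 from 0.170% ± 0.164 and TRBV12-2 to 0.762% ± 0.745 from 0.0494% ± 0.0408 (SD, n = 6 and n = 8). For TRBV13-2, TRBV13-1 and TRBV12-2, NTB untreated 4 was the highest library, with 9.35%, 4.41% and 2.07%. TRBV4 fell to 3.40% ± 0.709 from 6.37% ± 1.26, and TRBV2 to 7.03% ± 1.43 from 9.37% ± 1.26. The largest clones were TRBV19 TRBJ2-7 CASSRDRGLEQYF, with 1.67% of NTB untreated 2 (2.81% of reads, Wilson 95% interval 2.78% to 2.85%), and TRBV2 TRBJ2-4 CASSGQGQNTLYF, with 1.44% of NTB untreated 5 (1.40% of reads, Wilson 95% interval 1.37% to 1.42%).

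By exact permutation test NTB untreated samples and control tumours differed in clonality (-0.118, adjusted p = 0.00685), the 10 largest clones (-17.7 points, adjusted p = 0.0032), the largest clone (-5.66 points, adjusted p = 0.0124), expanded clones (-22.9 points, adjusted p = 0.0032) and richness (1.91 on the log2 scale, adjusted p = 0.00533), and in each of these all 6 libraries lay outside the range of the 8 control libraries. CDR3 length differed by -0.371 residues (13.83 ± 0.0896 against 14.20 ± 0.0573; exact permutation, adjusted p = 0.0032), again in 6 of 6 libraries, while the total count did not pass (-0.77 on the log2 scale, adjusted p = 0.266). Limma called 8 of 20 V segments. The 6 higher ones were TRBV13-2 (log2 change 3.16, adjusted p = 0.000124), TRBV13-1 (2.37), TRBV12-2 (2.12), TRBV16 (1.98), TRBV15 (1.52) and TRBV14 (1.41), and the 2 lower ones were TRBV4 (-0.89, adjusted p = 0.000124) and TRBV2 (-0.42, adjusted p = 0.0117). In list A 6 members were called over all segments and 6 adjusted over the list alone. In list B, the usual partners of the invariant NKT cell alpha chain, these counts were 1 and 1, and in list C 2 and 3. The list B call was TRBV13-2, and the list C calls over all segments were TRBV13-1 and TRBV13-2. These are list A members counted again and not separate signals. Without list A segments list B stood at 19.2% ± 3.27 against 18.4% ± 1.92. The sum of list A was 9.60% ± 9.40 (SD, n = 6) against 2.21% ± 0.780 (SD, n = 8), with p = 0.00766 and an adjusted p of 0.0574 in the exact permutation test; it ranged from 1.64% to 26.95% between NTB untreated libraries. List C rose to 14.2% ± 4.31 from 7.21% ± 0.548 (exact permutation, adjusted p = 0.005, 6 of 6 libraries), and TRBV19 alone, once list A segments were left out, still passed. Without list A segments TRBV4 (-0.78) passed and TRBV2 (-0.30) did not. Without NTB untreated 4, the library at 26.95%, TRBV14 (0.99) and TRBV2 (-0.31) no longer passed, and TRBV2 stood at 0.000682 when weighted by abundance. Limma called 0 of 12 J segments, with 2 at an unadjusted p under 0.05.

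**Figure D3:**
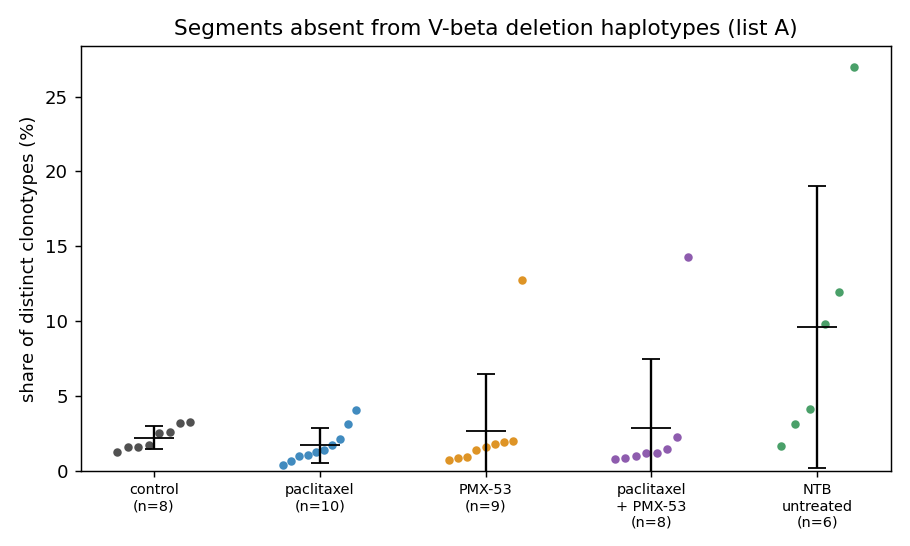
Summed usage of the 9 list A V segments as a percentage of distinct clonotypes, per library (points) and group, with mean and SD (black). Above the highest control library at 3.29% lie paclitaxel 1 at 4.06%, PMX-53 9 at 12.7%, combined treatment 4 at 14.3% and NTB untreated 1, 2, 4 and 5 at 9.79%, 11.96%, 26.95% and 4.12%.

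The remaining list tests gave no call. In the drug comparisons the sum of list A was 1.69% ± 1.14 under paclitaxel, 2.65% ± 3.82 under PMX-53 and 2.86% ± 4.63 under both drugs, against 2.21% ± 0.780 in control. PMX-53 9 (12.7%) and combined treatment 4 (14.3%) lay far above their groups, and the direction was not stable. With 1 library left out at a time, the difference from control ran from -0.826 to 0.676 points for PMX-53. For both drugs it ran from -0.977 to 0.948 points. List B stood at 18.1% ± 1.88 in control, 17.3% ± 1.14 under paclitaxel, 19.4% ± 2.97 under PMX-53, 19.2% ± 2.89 under both drugs and 20.2% ± 4.05 in NTB untreated samples. J cluster 1, list D, stood at 22.9% ± 1.12 in control, 21.8% ± 2.07 under paclitaxel, 22.9% ± 1.71 under PMX-53, 23.2% ± 1.44 under both drugs and 23.5% ± 1.24 in NTB untreated samples, and list E is its complement. Apart from the list members already named or counted, limma called 0 members of lists A to E in the 6 contrasts, over all segments and adjusted over the list alone alike. The percentage of clonotypes with hydrophobic residues at both CDR3 positions, a feature described for self-reactive T cells, was 2.32 ± 0.838 in control, 2.25 ± 0.491 under paclitaxel, 2.05 ± 0.415 under PMX-53, 2.45 ± 0.419 under both drugs and 1.82 ± 0.144 in NTB untreated samples (SD), with no difference past the threshold.

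Mice shared few clonotypes. The mean Jaccard overlap was 0.706% between control mice, 0.865% between mice under paclitaxel, 0.548% under PMX-53, 0.681% under both drugs and 3.08% between NTB untreated mice. Within-group overlap of NTB untreated and control mice exceeded the overlap between these groups by 0.892 points (permutation of mice, p = 0.00283, adjusted p = 0.0170). With 545 clonotypes drawn from every library of these groups the excess was 0.204 points, past the threshold as well, but the overlap was then 0.482% between NTB untreated mice and 0.429% between control mice. At equal depth in reads these libraries had held 3598 and 1063.5 such clonotypes on average. In the 5 drug contrasts the overlap tests did not pass, with a lowest adjusted p of 0.0915. The clonotypes found in most mice were TRBV24 TRBJ2-2 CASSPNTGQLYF in 30 mice, TRBV4 TRBJ2-7 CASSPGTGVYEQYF and TRBV5 TRBJ2-5 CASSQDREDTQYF in 26 each, TRBV24 TRBJ1-2 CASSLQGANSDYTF in 25 and TRBV2 TRBJ2-5 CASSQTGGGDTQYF in 22.

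Of 961 clonotypes present in at least 4 mice, Fisher's exact test called 0 in each of the 5 drug contrasts, with 4 at an unadjusted p under 0.05 for paclitaxel against control, 5 for both drugs against paclitaxel and 0 in the other 3. It called 10 between NTB untreated and control mice, out of 129 at an unadjusted p under 0.05. All 10 were found in 6 of 6 NTB untreated mice and 0 of 8 control mice at equal depth (exact p = 0.000333, adjusted p = 0.0320). They were TRBV1 TRBJ2-1 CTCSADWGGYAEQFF, TRBV1 TRBJ2-4 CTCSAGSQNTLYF, TRBV24 TRBJ2-1 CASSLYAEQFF, TRBV24 TRBJ2-7 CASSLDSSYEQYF, TRBV26 TRBJ2-7 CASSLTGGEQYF, TRBV3 TRBJ2-7 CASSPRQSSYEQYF, TRBV5 TRBJ1-1 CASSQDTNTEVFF, and TRBV5 TRBJ2-7 with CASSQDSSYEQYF, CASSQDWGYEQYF and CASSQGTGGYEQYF. In the full tables without thinning 0 clonotypes were called, and 5 of the 10 were present in control mice: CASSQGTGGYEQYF in 3, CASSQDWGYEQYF in 2, and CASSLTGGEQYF, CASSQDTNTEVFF and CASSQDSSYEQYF in 1 each. Presence was compared at equal reads, not at equal numbers of clonotypes, of which NTB untreated libraries held more.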

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

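Of the tests in this part, those on carry-over of library DNA and on the V segment mix were set before their results were seen. Thinning of CDR3 length was an alternative chosen beforehand; its use as a test of depth was chosen after the result was seen, like the other tests of explanations, the CDR3 length without single-read clonotypes and the other splits. In 60 tests of a group for a library far from the others, 12 gave one. About 3 would be due to chance if the tests were independent. They were not, since measures and lists overlap and some libraries were flagged more than once. The difference between 12 and 3 is therefore no measure of an excess.

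A family of TRBV4 TRBJ2-7 clones with CDR3 sequences of the form CASSxGTGVYEQYF was large in most libraries of the 4 tumour groups. It was almost absent from NTB untreated samples. Its mean share of the normalized count was 5.57% ± 7.82 (SD) in control, 2.75% ± 2.78 under paclitaxel and 6.35% ± 9.52 under PMX-53. Under both drugs it was 6.08% ± 7.76 and in NTB untreated samples 0.000787% ± 0.00078. The family exceeded 0.1% of reads in 26 of 35 tumour libraries. No read of it was found in PMX-53 5 and combined treatment 3 and 8. Paclitaxel 2 (0.000289% of reads), paclitaxel 5 (0.0006%) and PMX-53 6 (7.12e-05%) also lay below the highest NTB untreated library. The exact permutation test of means between control and NTB untreated missed the threshold on normalized counts (p = 0.0766) and on reads (p = 0.0976). On reads the libraries of these groups did not overlap (lowest control library 0.0316%, highest NTB untreated one 0.000833%). The exact permutation test on ranks, picked with the values in view, gave p = 0.000666. All family clones have the same V and J pair and so nearly the same factor in every library. The authors' normalization could therefore hardly have made this difference, and the rank test adds nothing on it as a cause. Carry-over of library DNA is argued against because only 1.25% of the richer library's other large clones (3 of 240) were found at the level it needs, and carry-over of 1 clone because, among 17 nucleotide sequences above 0.1% of reads, the commonest was in 4 of 25 libraries (16%). Carry-over of several clones cannot be told apart from separate origins: in 17 of 25 libraries (68%) the largest family clone had a nucleotide sequence found in another one, above the 50% set for excluding it, while in 8 it did not. The tests of carry-over of clones, of normalization and of the group difference were revised after their results were seen, and no drug comparison of the family passed the permutation test.

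The V segments of list A made up 12.7% of clonotypes in PMX-53 9 (Wilson 95% interval 11.7% to 13.9%; next library 1.98%) and 14.3% in combined treatment 4 (11.9% to 17.1%; next 2.25%), and up to 26.95% (26.0% to 27.9%) in NTB untreated libraries. Misassigned segments or sequencing errors are argued against: 99.3% of list A clonotypes with TRBJ2-7 and at least 5 reads ended in GAACAGTACTTC, against 1.33% of clonotypes with other V segments. Carry-over within the series is argued against as the whole cause in these tumour libraries, since 87.8% of the list A nucleotide clonotypes of PMX-53 9 and 61.6% of those of combined treatment 4 (Wilson 95% interval 51.8% to 70.6%; other V segments 76.1%) were in no other library, but for part of combined treatment 4 it stays open; this test, too, was revised after its result was seen. List A clonotypes had a median of 1 read in each control library, where the other V segments had medians of 3 to 41. In NTB untreated libraries the list A medians were 40 to 147 reads. A candidate explanation is DNA of a second haplotype of the receptor locus. No germline sequence of the FVB locus was at hand to compare. The list A share and the share of the rarer TRBJ2-7 ending outside list A rose together over 35 tumour libraries (Spearman rho 0.499, permutation p = 0.00238; Pearson r 0.916, p = 1e-05, the smallest the permutations can give; without the 2 farthest rho 0.391 and r 0.584) and over 6 NTB untreated ones (rho 0.943, permutation p = 0.0159; r 0.973, p = 0.00399; without the 2 farthest rho 0.80 and r 0.909). Whether such DNA came from mixed breeding, from other animals or from outside the series stays open, and 5 of 6 NTB untreated libraries exceeded the highest control library (0.855%) in that rarer ending, a signal outside the report's comparisons. The beta chain CDR3 of the P14 transgenic mouse line, TRBV13-3 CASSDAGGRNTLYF, was found in 17 libraries. Its share was highest in combined treatment 4, with 0.508% of reads. It was encoded by 11 nucleotide sequences over the series, and its presence does not settle the source. The OT-I sequence was in 1 library, PMX-53 7, with 28 reads.

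The mean CDR3 was shorter in both PMX-53 groups, by -0.242 residues (SE 0.0346) for both drugs against control. At equal depth the difference was -0.0380 (SE 0.0277; exact permutation p = 0.195), so read depth may explain most of it; for PMX-53 alone it was 0.00612. A different V segment mix is argued against, since at one mix the difference was -0.260 (exact permutation p = 0.000155). Without single-read clonotypes the difference was -0.0890 for both drugs (exact permutation p = 0.00311) and -0.0265 for PMX-53 alone (exact permutation p = 0.358), so a smaller difference stays open for both drugs.

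The other libraries far from their group were control 1, with 40.8% in the 10 largest clones (next 27.6%), and combined treatment 2, with 23.1% in the largest clone (next 10.8%). PMX-53 9 had 26.6% of clonotypes in list B (next 21.2%) and 12.8% in list C (next 10.3%), and paclitaxel 1 had 26.5% in list D (next 23.0%). Combined treatment 4 had the lowest mean CDR3 length of its group, 13.8 residues (next 13.9), and NTB untreated 1 the highest, 13.995 (next 13.8). NTB untreated 4 had a clonality of 0.0857 (next 0.113), a total count of 18.71 on the log2 scale (next 20.001) and 28.2% of clonotypes in list B (next 20.7%).

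Other splits of the same libraries tested whether chance can be excluded for each count of calls, with 100 splits per contrast, the real one included. For NTB untreated against control no other split gave as many V calls (8 calls, highest other split 5, 1 of 100 as large). The same held for shared clonotypes at equal depth and from 4 mice up (10 calls, highest other 0, 1 of 100). However, 0 were called from 3 mice up or without thinning. As 1 of 100 is the smallest share that 100 splits can give, chance is argued against but not excluded. Of the 8 V calls 6 were list A segments, and without list A the V calls were 2. For V usage under PMX-53 against control 4 of 100 splits gave at least its 1 call, a share under 0.05, but the highest other split gave 4 calls, more than the real one, so chance is not taken as excluded; the call, TRBV12-1, was also lost at equal depth (-0.08). By number of calls, chance cannot be excluded for V usage of both drugs against control (1 call, 10 of 100, highest other 1) or against paclitaxel (1 call, 6 of 100, highest other 1). Nor can it be for J usage of both drugs against paclitaxel (1 call, 13 of 100, highest other 2) or against PMX-53 (1 call, 12 of 100, highest other 3). The splits compare numbers of calls and not their strength. With 1 call they cannot weigh how far past the threshold that segment, such as TRBV26, lay. Where limma or Fisher's test made 0 calls, all 100 splits gave at least as many; the highest other split had 1 call for V usage under paclitaxel, 3 for V usage of both drugs against PMX-53, 1 for J usage in the 4 contrasts concerned and 0 for shared clonotypes.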

How the results depend on the processing

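The settings using the second normalized column, leaving out libraries under 100000 reads, leaving out list A, thinning of J usage and lists, and leaving out 1 library for the lists were chosen after seeing the data. Outside the leave-one-out settings, 679 measures, lists, overlaps and counts of calls were recomputed. Of these, 612 kept their side of the threshold or, for counts, changed little, 32 counts moved, 24 no longer passed, 8 newly passed and 3 reversed. A change of direction was counted as reversed only where the value passed before or after. The 612 therefore include changes of direction. Clonality of both drugs lay below control (0.209 against 0.232) but above it when thinned (0.181 against 0.157). Of 106 values of single named segments, 89 kept direction and threshold, 14 no longer passed and 3 reversed. By the same rule NTB untreated against control kept 280 of 298, leave-one-out settings included. Unless stated, the cause was not tested.

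Thinned to equal depth, CDR3 length under PMX-53 against control reversed to 0.00612 residues, and for both drugs it did not pass against control (-0.0380) or paclitaxel (-0.0421). V calls were 0 for PMX-53 against control and 0 for both drugs against paclitaxel; J calls were 1 for NTB untreated, 0 for both drugs against paclitaxel and 1 for paclitaxel. List A (9.50 points) and list B (4.73) newly passed for NTB untreated, and list C (1.84) no longer passed for both drugs.

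Weighted by abundance, CDR3 length reversed for PMX-53 (0.121) and for both drugs against control (0.0484) and did not pass against paclitaxel (-0.107). TRBJ2-7 reversed for both drugs against paclitaxel (0.21), as did TRBV12-1 under PMX-53 (0.0385) and TRBV2 in NTB untreated (0.000682), none past the threshold in that direction. V calls were 3 for PMX-53, 2 for both drugs against control, with TRBV26 (-0.20) not among them, 0 against paclitaxel and 1 for paclitaxel; J calls were 2 for PMX-53, 0 for both drugs against PMX-53, 6 against control, 2 against paclitaxel and 1 for paclitaxel. Newly past were list A (5.28 points), list D (3.39) and list E (-3.39) for NTB untreated and list C (3.47) for paclitaxel.

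Pairing same-numbered animals left 6 to 8 pairs; with 6 pairs the smallest possible p was 0.0312, which by construction ended the calls for NTB untreated: clonality -0.111, 10 largest clones -18.3 points, largest clone -6.01, expanded clones -23.5, richness 2.16, CDR3 length -0.346 and list C 7.08. It also ended CDR3 length for PMX-53 (-0.157) and for both drugs against control (-0.242) and paclitaxel (-0.206), the total against control (-2.35) and paclitaxel (-2.35), and list C for PMX-53 (1.74) and both drugs (2.50). CDR3 length and the total of both drugs against control, and list C for PMX-53 and both drugs, had a paired p of 0.0078. This is the smallest that 8 pairs allow, so the paired test could not have given them a lower one. V calls for both drugs against control were 2 and J calls against PMX-53 0. The numbers did not pair the samples: between 2 and 5 of 6 to 8 pairs per contrast had a correlation above 0.1.

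Without libraries under 100000 reads (PMX-53 3 and combined treatment 4, 5 and 7) both drugs no longer passed in the total against control (-1.22) and paclitaxel (-1.26) or in CDR3 length (-0.162), TRBV26 (-0.51) and TRBJ2-7 (-0.09) against paclitaxel; V calls were 2 against control and 0 against paclitaxel, and J calls 0 against paclitaxel and 0 against PMX-53. Without list A segments, which by construction leaves list C with TRBV19 alone, list C did not pass for PMX-53 (1.29) or both drugs (1.69), CDR3 length did not for PMX-53 (-0.101), and V calls were 2 for NTB untreated, with TRBV4 (-0.78) but not TRBV2 (-0.30) among them, 0 for PMX-53 and 2 for both drugs against control.

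With only the 2 groups in the fit, V calls were 2 for PMX-53, 3 for both drugs against control and 1 for paclitaxel, and J calls 0 for both drugs against PMX-53 and 0 against paclitaxel. A pseudocount of 0.5 gave 0 V calls for PMX-53. The second normalized column made expanded clones pass for both drugs against paclitaxel (11.1 points), and ranks made CDR3 length pass against PMX-53 (-0.0840). Shared clonotypes for NTB untreated numbered 0 from 3 mice up, 32 from 6 mice up and 0 without thinning.

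Leaving out 1 library was run for the repertoire measures, the interaction, V usage and the lists, but not for J usage, overlap or shared clonotypes. By the rule above it kept 1649 of 1680 values, with 9 counts moved, 9 values newly past and 13 no longer past. Values that passed neither before nor after could change direction and still count as kept. Of 163 values of single segments 156 were kept, with 7 no longer past. The 13 were all list C of both drugs against control, which ranged from 1.92 to 2.85 points and did not pass without any 1 control library or combined treatment 2, 3, 4, 7 or 8 (1.92 to 2.63). List A for NTB untreated ranged from 3.92 to 8.98 and passed without NTB untreated 6 (8.98); list B of both drugs against paclitaxel ranged from 1.32 to 2.58 and passed without combined treatment 6 (2.58). For both drugs against paclitaxel, richness ranged from -1.11 to -0.76 and passed without paclitaxel 1 (-1.11); the 10 largest clones ranged from 5.42 to 8.85 points and passed without paclitaxel 3 (8.71); expanded clones ranged from 7.10 to 10.2 and passed without paclitaxel 3 (9.86), combined treatment 3 (10.1) or 5 (10.2). CDR3 length of both drugs against PMX-53 ranged from -0.109 to -0.0576 and passed without PMX-53 1 (-0.109), and the total of PMX-53 against control from -1.74 to -1.07, passing without PMX-53 5 (-1.74). V calls ranged from 0 to 2 for PMX-53 (0 without control 1, 2 or 3 or PMX-53 3 or 8; 2 without PMX-53 5 or 6), from 1 to 2 for both drugs against control (2 without combined treatment 4) and from 1 to 2 against paclitaxel (2 without combined treatment 3). TRBV12-1 under PMX-53 did not pass without PMX-53 3 (-1.21), PMX-53 8 (-1.33), control 1 (-1.47), control 2 (-1.43) or control 3 (-1.44), nor TRBV14 (0.99) and TRBV2 (-0.31) in NTB untreated without NTB untreated 4.

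Not run were the alternatives with non-productive clonotypes, since every deposited CDR3 was in frame, and without libraries under 5000 reads, since none was. At 32773 reads, rare clonotypes went unseen in the deeper libraries.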

Other observations

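The sequences below were picked after seeing the data. Among clones above 0.5% of a library, 7 combinations of V segment, J segment and last 9 CDR3 residues recurred in at least 5 libraries. None was among such clones of NTB untreated samples, whose 10 largest clones held 6.09% of the normalized count, against 23.8% in control. The size cut thus works against NTB untreated samples, and absence from them cannot be read from it. TRBV4 TRBJ2-7 GTGVYEQYF occurred in 24 libraries (5 control, 7 paclitaxel, 6 PMX-53, 6 both drugs), TRBV24 TRBJ2-2 SPNTGQLYF in 10 (4, 1, 2 and 3), TRBV3 TRBJ2-5 LGVQDTQYF in 9 (4, 1, 1 and 3) and TRBV4 TRBJ2-7 GTGAYEQYF in 7 (4, 0, 1 and 2). TRBV3 TRBJ2-4 RQSQNTLYF, TRBV5 TRBJ2-1 QDGDAEQFF and TRBV5 TRBJ2-7 DRQGGEQYF occurred in 5 each. Over all clone sizes TRBV24 TRBJ2-2 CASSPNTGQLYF was in 3 NTB untreated mice, TRBV4 TRBJ2-7 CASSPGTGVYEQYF in 2 and TRBV4 TRBJ2-7 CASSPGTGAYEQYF in 1. Over all clone sizes, too, TRBV4 TRBJ2-7 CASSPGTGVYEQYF was encoded by 8 nucleotide sequences and TRBV2 TRBJ2-5 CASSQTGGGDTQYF by 20.

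TRBV26 clonotypes had a median of 2 reads in control, paclitaxel, PMX-53 and NTB untreated libraries and 3 under both drugs, against 5, 38, 58, 45 and 59 for the other V segments of these groups in that order. The authors' factor for TRBV26 with TRBJ2-3 was 74.8 and that for TRBV4 with TRBJ2-7 was 3.69.

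Combined treatment 5 shared 451 of its 1258 nucleotide clonotypes (35.9%) with paclitaxel 9 and 265 (21.1%) with paclitaxel 10, a comparison made, like its test, after seeing the data. All 20 of the 20 largest clones of paclitaxel 9 (100%) were found in combined treatment 5, and 0 of the 20 largest the other way; with paclitaxel 10 these counts were 19 and 1. The clonotypes shared with paclitaxel 9 had a median of 439 reads there and 1 read in combined treatment 5, where they held 1.68% of reads. This is consistent with carry-over of paclitaxel 9 material into combined treatment 5, at a stage the files do not show. Removing clonotypes at least 100 times more frequent in another library took out only 10.3% of the clonotypes of combined treatment 5, so that setting did not remove most of the shared ones. Clonotypes shared with paclitaxel 10 likewise had a median of 791 reads there and 1 read in combined treatment 5. A weaker pattern of this kind linked paclitaxel 5 and combined treatment 8, which shared 42 clonotypes. Of the 20 largest clones of paclitaxel 5, 10 were in combined treatment 8, and 2 the other way. Their shared clonotypes had medians of 611 reads and 1 read. Leaving out combined treatment 5 therefore does not remove every library with this pattern.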
